A study of Mus musculus with 4 samples.

How the data were processed

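RNA of cultured mouse splenocytes was measured on 4 Agilent 1-colour (Cy3) arrays of design 026655, 2 with 10 µM imatinib and 2 without. Per the labels, RNA was extracted with RNeasy columns, and 1650 ng of labelled cRNA was hybridised for 17 h at 65 °C. The deposited scanner files hold fluorescence intensity per spot, made by the authors with Feature Extraction 9.1.3.1; the processed signal in them is background-subtracted and detrended within each array and not scaled between arrays. The deposited value table holds log2 values, made by the authors in GeneSpringGX (version not stated) as log2 of the processed signal minus the 75th percentile of each array. This was checked against the scanner files: each column matched log2 of the processed signal minus 1 constant within 0.01 for 99.88% to 99.93% of the probes (r of at least 0.9999). The medians of its columns were -4.00 and -3.92 for imatinib and -4.10 and -4.17 for control.

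Values were computed from the scanner files. Control spots were left out, the log2 processed signals of spots with the same probe were averaged without spots marked as outliers, and the 75th percentile of the array was subtracted. A probe was tested if it was well above background on both arrays of at least 1 group; 25467 probes were, and 92 of them were left out for a marked value. The 254 probes spotted 10 times differed between replicate arrays with an SD of 0.094 (imatinib) and 0.13 (control), against 0.048 and 0.059 expected from the spread of their spots and 0.62 to 0.65 between groups. All 4 arrays lay on 1 slide, with the control arrays at positions 1 and 3 and the imatinib arrays at positions 2 and 4.

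Imatinib and control arrays were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, group as the only term, two-sided), with Benjamini-Hochberg adjusted p under 0.05 as the threshold and a log2 difference of at least 1 as the size threshold for 2-fold changes. The fit had 2 residual degrees of freedom and 2.05 prior ones, with a prior SD of 0.079. SD and SE in the text are on the log2 scale. A gene that was well above background on both arrays of 1 group and on neither array of the other is given as a bound. On each array of the dim group, the floor was the lowest signal of any probe called well above background. The fold was taken against the higher of this floor and the signal of the gene itself. The bound holds for the processed signal, and another background correction can give a smaller difference. For gene lists and counts of genes the probe with the highest mean signal stood for its gene; of 1850 genes with several probes and a change, 58 had another probe that passed in the opposite direction. Probes were named from the RefSeq table of assembly GRCm38.p6 by accession (26055), symbol (3195) or synonym (930), and 9249 of the 39429 probes kept the name in the files alone. No coordinates are given.

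The 35 gene lists, 24 of programmes and 11 of cell type markers, the test and most alternative settings were fixed before the data were examined. Lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 35 lists; the adjusted p of a list in the text is from camera at the preset correlation unless another is named. The lists hold 909 symbols, of which 891 matched a probe and 785 were tested. Counts of members up and down are over all probes tested, and counts adjusted over the list alone stand beside them. Named genes followed a rule fixed in advance: genes named by the study, such as Tcf3, with all probes; the 10 largest rises and 10 largest falls among genes above background on all 4 arrays, without overlap of the groups and with a plain gene symbol; the 3 genes per direction with the brightest signal in the other group as bounds; and up to 4 members of each list with the largest change past the threshold, members measured on all arrays taken first. Further members were added after their values were seen: Cd4, Cd247, Apoe, C1qb, Csf1r, Mpeg1, Siglec1, Cd79a, Cd79b, Igkc and Ighm. Members of multigene families with close relatives are named as uncertain, cross-hybridisation was not analysed here, and a few genes under this rule are not reported here.

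After the values were seen, probe sequences were searched for perfect runs of at least 12 bases of a repeated 2-base or 3-base unit, since a band of bright probes rose together. Such a run was found in 109 tested probes with a TG unit, 23 with AG, 63 with AAG, 50 with AC, 16 with TC, 1 with CTT and 109 with another unit, whose median difference was 0.11 (25 up and 19 down).

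The alternative settings fixed in this way were normexp background correction with an offset of 50, quantile normalization, median centring, no filter on dim probes, only probes above background on all 4 arrays, the replicate number as a block, each array left out in turn, the deposited value table, a variance model with trend and robust fitting, genes in place of probes, and, for lists, an estimated correlation, fry and the mean of the probes of a gene. Alternatives added after seeing the data were scaling on 8 spike-in transcripts, crossed pairing of the replicates, marked spots kept, lists without members of cell type lists and repeat probes left out. With 3 arrays the lone array of a group is assumed to vary like the others.

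The steps were tested on simulated data with the size and spread of the real arrays. With 200 of 25375 probes changed, the test called 0 of 67 probes changed by 0.5 on the log2 scale, 26 of 67 changed by 1 (38.8%) and 54 of 66 changed by 2 (81.8%), with 2 unchanged probes called. With 40% of the probes changed, it called 80.2%, 95.1% and 99.0% of those sizes, and 2.76% of the calls were false. Those sizes were about equally frequent. In the data, the 10622 probes past the threshold had a median absolute difference of 0.51, and 1876 of them reached 1. The simulated shares therefore need not hold for the real arrays. With 1 of 35 lists shifted by -0.4 over 20500 genes, camera called 0 of the 34 unshifted lists. It gave the shifted list an adjusted p of 2.4e-33 with the preset correlation and 0.22 with an estimated correlation. Genes were simulated independently of each other. The simulation therefore cannot show how often the preset correlation gives false calls where genes vary together. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.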

Results

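Spleen cells of 8-week-old female C57BL/6 mice were cultured for 72 h in medium with IL-4 and LPS, which activate B cells and start class switch recombination. Imatinib, an inhibitor of the kinases ABL, KIT and PDGFR, was present at 10 µM in one group and absent in the control group. RNA of each group was measured on 2 Agilent 1-colour arrays, and the labels do not say whether the 2 samples of a group came from separate animals or cultures. Each array carried 43020 spots for 39429 mouse probes. On the imatinib arrays, 25192 and 26762 probes were well above background, and on the control arrays 25336 and 25018 were. The 75th percentile of the processed signal was 699 and 678 on the imatinib arrays and 739 and 854 on the control arrays, and no spot was saturated. Pearson's r across probes was 0.994 within each group and 0.986 to 0.988 between groups (probes are not independent replicates). The number of arrays limits the precision of every value, and an exact permutation test of 2 against 2 arrays cannot give a two-sided p under 0.333.

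The labels name E2A among the factors of interest, and the first question was whether imatinib lowered Tcf3, which encodes the E2A transcription factors. Tcf3 was lower with imatinib on both of its probes. Its normalised log2 signal, relative to the 75th percentile of the array, was 1.82 ± 0.029 with imatinib and 2.27 ± 0.030 without on probe A_51_P394471 (SD, n = 2 arrays each), with 1.84 and 1.80 on the imatinib arrays and 2.25 and 2.29 on the control arrays, a log2 difference of -0.45 (SE 0.060, adjusted p = 0.0095). The size depends on the scaling, at -0.355 under quantile normalization, -0.67 under median centring and -0.73 under spike-in scaling. The second Tcf3 probe, A_55_P1975354, differed by -0.51 (SE 0.059, adjusted p = 0.0073). The call for Tcf3 on the first probe ended without imatinib 1 (adjusted p = 0.082) and without imatinib 2 (adjusted p = 0.074), and over all alternatives its adjusted p ran from 2.1e-05 to 0.082.

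**Figure D1:**
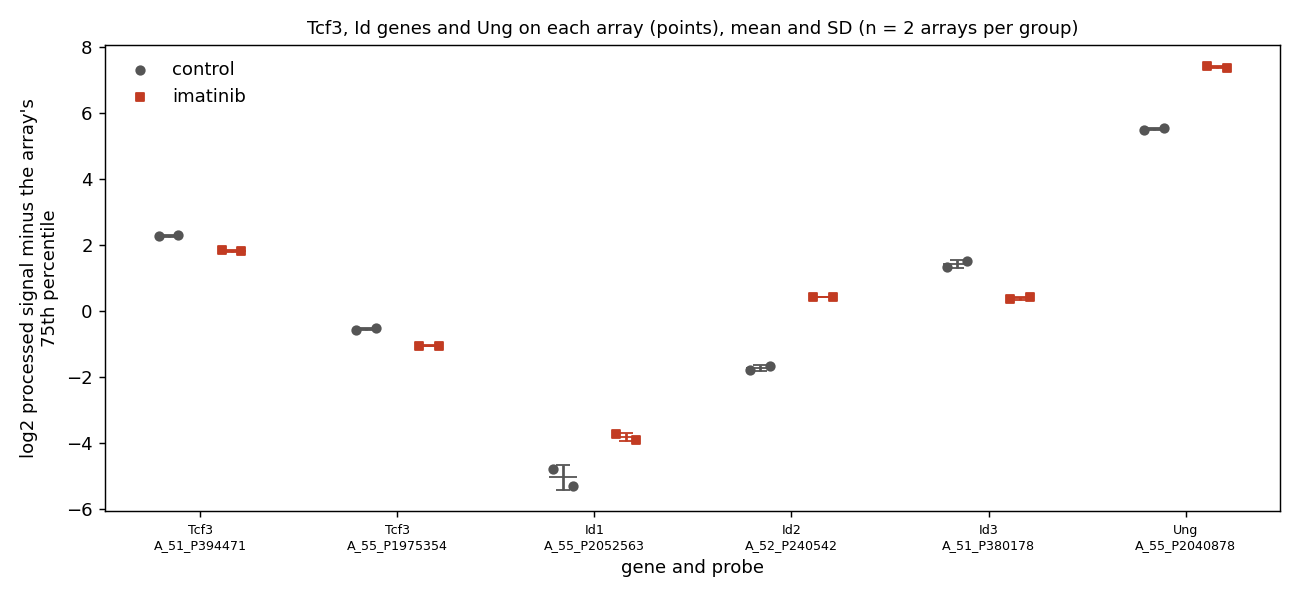
Normalised log2 signal (y axis, log2 processed signal minus the 75th percentile of the array) of each probe of Tcf3 and of the brightest probe of Id1, Id2, Id3 and Ung (x axis), with points for single arrays and bars for the mean and SD of 2 arrays per group. The first Tcf3 probe lay at 1.80 to 1.84 with imatinib and 2.25 to 2.29 without, Id2 and Id3 moved in opposite directions, and the Ung probe holds a TG repeat shared by other probes that rose.

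A large share of the transcripts differed between the imatinib and control arrays. The labels leave open whether the 2 samples of a group were separate cultures, and if not, the p-values measure technical spread alone. A difference between single cultures could then not be told apart from an effect of imatinib. Of 25375 probes tested, 10622 passed an adjusted p of 0.05 in the limma fit, 4905 of them higher and 5717 lower with imatinib. At least 2-fold changes numbered 1547 higher and 329 lower, against 1209 and 694 under median centring and 1123 and 890 under spike-in scaling. At the level of genes, 3980 rose and 4450 fell out of 20500. Arrays of the 2 groups did not overlap for 73.7% of the probes, where chance gives 33.3%. The split into rises and falls depends on the scaling. Spike-in scaling, chosen after seeing the data, moved the median of all probes by -0.28 and gave 2802 higher and 11739 lower. Median centring moved it by -0.22 and gave 3124 higher and 10003 lower. The number of changed probes was 2529 without imatinib 1, 3886 without imatinib 2, 8477 without control 1 and 6445 without control 2. The number at least 2-fold lower was 535 without control 1. A different background correction (normexp, whose offset shrinks differences of dim probes) left 793 probes at least 2-fold changed. With normexp, 46 of 146 genes compared singly had a difference more than 1.5 times smaller.

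**Figure D2:**
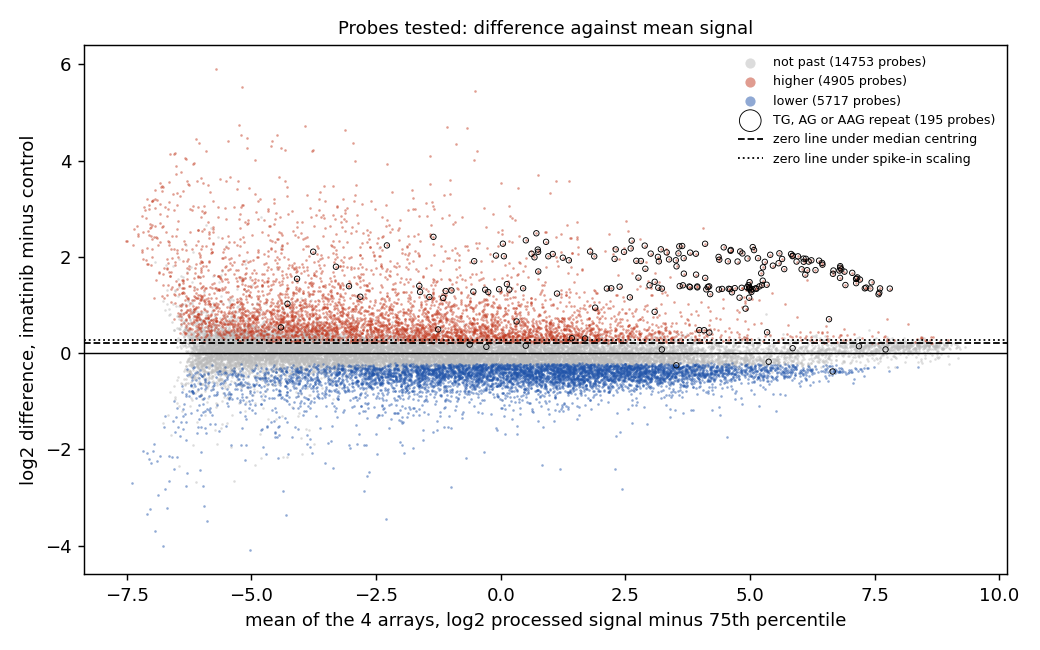
Log2 difference, imatinib minus control (y axis), against the mean normalised log2 signal of the 4 arrays (x axis) for the 25375 probes tested, with 4905 higher probes in red, 5717 lower probes in blue and the rest in grey. Dashed and dotted lines mark where the zero would lie under median centring (a shift of -0.22) and spike-in scaling (a shift of -0.28), and black circles mark 195 probes with a TG, AG or AAG repeat, whose median difference was 1.56.

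The largest rises among genes above background on all arrays included products of macrophages and other myeloid cells. Chil3 (Chi3l3 in the files), a chitinase-like protein of alternatively activated macrophages, rose by 5.45 on the log2 scale (SE 0.073), from -3.23 ± 0.077 to 2.21 ± 0.053 (SD, n = 2 arrays each). Its family has similar members, so the target is uncertain. The chemokine gene Ccl1 rose by 4.71, Gpnmb, a lysosomal glycoprotein of macrophages, by 4.64, Clec7a, the beta-glucan receptor dectin-1, by 4.36, and Pf4, platelet factor 4, by 4.35. Kifc3 (a kinesin, 4.21), Mmp8 (neutrophil collagenase, 4.2025), Ahr (the aryl hydrocarbon receptor, 4.01), Cd63 (a lysosomal tetraspanin, 3.70) and Adgre1 (the macrophage antigen F4/80, Emr1 in the files, 3.60) completed the 10. Markers of T cells and macrophages rose in the same arrays, with median log2 differences of 1.95 and 2.20. Ccl7, Irs1 and Cyp1a1 were not above background in the control group. On the processed signal they were at least 26.2-fold, 17.8-fold and 15.4-fold higher with imatinib. For Ccl7 this equals the measured fold, since its own control signals lay above the floor. The largest adjusted p among these 13 genes was 0.0014. Sizes and order depend on the background correction. With normexp, Gpnmb, Clec7a, Kifc3 and Mmp8 differed by 2.69, 2.48, 1.91 and 2.20. Ccl7, Irs1 and Cyp1a1 then differed by 2.04, 1.74 and 1.60, less than their bounds.

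Among genes above background on all arrays, the largest fall was that of a probe for an immunoglobulin heavy chain variable family, Igh-VJ558, at -3.44 (SE 0.17), whose target is uncertain because the family has many similar members. Dkk3, a secreted protein related to Wnt inhibitors, fell by 2.87, and Mfap5, a microfibril protein, fell by 2.54. Sytl3, a synaptotagmin-like protein, fell by 2.40, from a signal of 3.49 ± 0.093 to 1.09 ± 0.0083. Differences of -2.33 for Grm6, -2.28 for Tmem26, -2.17 for Ttll9 and -2.07 for Padi3 also passed. Gbp2b (Gbp1 in the files), an interferon-inducible GTPase, differed by -2.07, and Serpina3f, a serine protease inhibitor, by -2.05. Both are uncertain as members of multigene families. Bace2, Vwa5b1 and Grtp1 were not above background with imatinib and were at least 11.2-fold, 4.92-fold and 3.61-fold lower. All 13 passed the threshold, with adjusted p up to 0.0083. With normexp the differences were -2.15 for Igh-VJ558, -1.70 for Dkk3, -1.64 for Mfap5, and -0.90 for Tmem26 and for Padi3. Those of Bace2, Vwa5b1 and Grtp1 were -0.99, -0.47 and -0.35, less than their bounds.

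Genes of class switch recombination and its DNA repair fell as a list. Of 38 measured members, 22 fell and 4 rose (25 and 4 adjusted over the list alone), with a median of -0.27 (-0.49 under median centring and -0.55 under spike-in scaling) and an adjusted p of 0.0011, or adjusted p = 0.23 with an estimated correlation. Apex1, an endonuclease of base excision repair, fell by 0.86, and Exo1, an exonuclease of mismatch repair, fell by 0.76. The only tested probe of Ung, a uracil glycosylase, differed by 1.87, but it holds a TG repeat of 34 bases, and the 109 probes with such a repeat had a median difference of 1.90, so this value is uncertain for Ung. Of 32 transcription factors of the E2A family and of B cell activation, 12 rose and 8 fell (12 and 8 adjusted over the list alone); the median of 0.15 turned to -0.07 under median centring and to -0.13 under spike-in scaling, and the list did not pass (adjusted p = 0.35). Id2, an inhibitor of E2A proteins, rose by 2.15 (SE 0.072), from -1.73 to 0.43, whereas Id3, another such inhibitor, fell by 1.04 (SE 0.082). Id1 differed by 1.22 and Cebpb by 0.99. The call for Id1 ended without imatinib 1 (adjusted p = 0.095), without imatinib 2 (adjusted p = 0.060) and without a filter on dim probes (adjusted p = 0.059). T cell and macrophage markers had medians of 1.95 and 2.20 in the same arrays.

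Immunoglobulin transcripts were measured by 5 genes of the list of constant regions and associated chains, since most constant region genes had no probe under a listed name. The joining chain gene Jchain (Igj in the files) fell by 0.85, Vpreb1 of the surrogate light chain differed by 0.66, and an Ighg probe, whose exact subclass is uncertain, by -0.48; Igkc and Ighm differed by -0.05 and 0.05 and did not pass. The list (1 up and 2 down, also adjusted over the list alone) had a median of -0.05 and an adjusted p of 0.47. The median was 0.09 with the other background correction, -0.27 under quantile normalization, -0.26 under median centring and -0.33 under spike-in scaling. Of 27 plasma cell genes, 5 rose and 10 fell (5 and 10 adjusted over the list alone), with a median of -0.09 (-0.31 under median centring and -0.38 under spike-in scaling) and an adjusted p of 0.19. Among them Prg2, a granule protein, fell by 1.53, Tnfrsf17, the survival receptor BCMA, fell by 0.70, and Cd28, which T cells also express, rose by 2.84. Without imatinib 1, Vpreb1, Ighg and Tnfrsf17 no longer passed (adjusted p = 0.056, 0.089 and 0.053), and Vpreb1 and Ighg also failed without imatinib 2 (0.078 and 0.062). Vpreb1 failed too without control 1 (0.063), without control 2 (0.11), without a filter on dim probes (0.083) and with the replicate block (0.062).

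Genes induced by IL-4 through STAT6 rose as a list. Of 25 measured, 10 rose and 2 fell (10 and 2 adjusted over the list alone), with an adjusted p of 0.0012, or adjusted p = 0.23 with an estimated correlation; the median of 0.19 turned to -0.03 under median centring and to -0.10 under spike-in scaling. Chil3, Gata3 (2.33), the signalling inhibitor Cish (2.15) and the chemokine gene Ccl17 (2.13) were among those that rose. The list shares 6 genes with cell type lists, whose T cell and macrophage medians were 1.95 and 2.20, and without shared genes its adjusted p was 0.035 in a comparison chosen after seeing the data. Targets of LPS and NF-kB signalling went both ways, with 13 up and 13 down of 36 (14 and 14 adjusted over the list alone). Their median was -0.07 (0.01 under quantile normalization, -0.29 under median centring and -0.36 under spike-in scaling) while the mean was 0.43 and the test pointed up (adjusted p = 0.94). The chemokine genes Ccl4 and Ccl3 rose by 3.32 and 2.85 and Lcn2, an iron-sequestering lipocalin, by 1.88, whereas Ltb, lymphotoxin beta, fell by 1.73.

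Markers of B cell activation and B cell receptor signalling did not pass as lists. Of 28 activation markers, 10 rose and 9 fell (10 and 9 adjusted over the list alone), and the median of 0.03 turned to -0.19 under median centring and -0.25 under spike-in scaling (adjusted p = 0.72). Tnfsf8, the CD30 ligand, rose by 1.57, the lymph node homing receptor Ccr7 by 1.36 and the chemokine receptor Cxcr4 by 1.17. The Tnfrsf9 probe with the highest signal differed by 2.22 but holds a TG repeat of 22 bases, and the other Tnfrsf9 probe differed by 0.79 (SE 0.088, adjusted p = 0.0067). Of 29 receptor signalling genes, 7 rose and 8 fell (10 and 8 adjusted over the list alone), with a median of -0.01 (0.01 under quantile normalization, -0.22 under median centring and -0.29 under spike-in scaling) and an adjusted p of 0.85. Syk, the kinase next to the receptor (Sykb in the files), fell by 1.15 and the inhibitory receptor Cd22 fell by 1.05, whereas the kinase gene Blk rose by 0.82. Lyn differed by -0.66, a call that ended without imatinib 1 (adjusted p = 0.089), without imatinib 2 (adjusted p = 0.065) and without a filter on dim probes (adjusted p = 0.052).

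Of 14 genes for targets of imatinib and their ligands, 6 rose and 1 fell (7 and 2 adjusted over the list alone), with an adjusted p of 0.028, or adjusted p = 0.40 with an estimated correlation; the median of 0.26 turned to -0.02 under spike-in scaling. Pdgfa, a PDGF ligand, rose by 3.11, the receptor kinase gene Kit by 1.77 and Lck, a T cell kinase, by 1.505, and Syk was the gene that fell. The call ended without imatinib 1 (adjusted p = 0.053) and without the 2 members that cell type lists also hold (adjusted p = 0.088, chosen after seeing the data); macrophage and T cell markers had medians of 2.20 and 1.95.

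Genes of cell division fell together, in arrays in which T cell and macrophage markers rose (medians 1.95 and 2.20). In mitosis, 29 of 36 genes fell and none rose (31 and 0 adjusted over the list alone), with a median of -0.39 (-0.61 under median centring and -0.67 under spike-in scaling) and an adjusted p of 5.6e-09, or adjusted p = 0.23 with an estimated correlation. The phosphatase gene Cdc25c fell by 0.88, and the spindle checkpoint and mitotic kinases Bub1b, Plk1 and Ttk fell by 0.85, 0.73 and 0.70. In DNA replication, 24 of 37 genes fell and 1 rose (28 and 2 adjusted over the list alone), with a median of -0.35 (-0.57 and -0.63 under these scalings) and an adjusted p of 1.9e-06, or adjusted p = 0.22 with an estimated correlation. Orc1 of the origin recognition complex fell by 0.63, the histone mRNA binding protein Slbp fell by 0.61, Dut fell by 0.55 and the clamp loader subunit Rfc4 fell by 0.54. The only tested Dut probe holds a GTT repeat of 13 bases. Targets of p53 and inhibitors of cyclin-dependent kinases had 9 up and 2 down of 24 (10 and 5 adjusted over the list alone) and a median of 0.01, which turned to -0.21 under median centring and -0.27 under spike-in scaling (adjusted p = 0.46). Cdkn1a, the inhibitor p21, rose by 1.27 and Plk2 by 0.92, while Cdkn1c differed by -0.67 and Gadd45a by 0.55. Without imatinib 1, Plk1, Ttk, Orc1, Slbp, Dut, Rfc4, Cdkn1c and Gadd45a no longer passed (adjusted p 0.051 to 0.097), and without imatinib 2 Orc1, Slbp, Dut, Rfc4, Cdkn1c and Gadd45a did not (0.054 to 0.089). Orc1 and Slbp also failed without control 2 (0.056 and 0.065), and Gadd45a under median centring (0.057) and spike-in scaling (0.093). With the other background correction Cdkn1c differed by -0.15 (0.090). Slbp did not pass with the replicate block (0.055), and Orc1, Slbp, Cdkn1c and Gadd45a did not without a filter on dim probes (0.051 to 0.069).

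Biosynthetic programmes fell as well, in the same arrays as the rises of T cell and macrophage markers (medians 1.95 and 2.20). Over the mitosis, DNA replication, ribosome biogenesis and cholesterol synthesis lists together, the median of 136 genes was -0.42. Random lists of genes with like signal had a median of -0.10, so not all of the fall is particular to these lists. In ribosome biogenesis, 26 of 32 genes fell and none rose (29 and 0 adjusted over the list alone), with a median of -0.51 (-0.72 under median centring and -0.79 under spike-in scaling) and an adjusted p of 4.6e-09, or adjusted p = 0.22 with an estimated correlation. Wdr12 and Nop14, factors of ribosome assembly, fell by 0.82 and 0.78, Nop16 fell by 0.78 and Polr1b, a subunit of RNA polymerase I, fell by 0.73. In cholesterol and fatty acid synthesis, 26 of 31 genes fell and 1 rose (the same counts adjusted over the list alone), with a median of -0.58 (-0.80 and -0.86 under these scalings) and an adjusted p of 2.1e-09, or adjusted p = 0.23 with an estimated correlation. The desaturase genes Scd1 and Scd2 fell by 1.48 and 1.21, the fatty acid elongase Elovl6 fell by 1.36 and lanosterol synthase, Lss, fell by 1.29. In the unfolded protein response, 17 of 26 genes fell and 1 rose (19 and 2 adjusted over the list alone), with a median of -0.37 (-0.59 under median centring and -0.65 under spike-in scaling) and an adjusted p of 3.5e-05, or adjusted p = 0.36 with an estimated correlation. The chaperone and oxidoreductase genes Dnajc3, Ero1b, Pdia3 and Hyou1 fell by 0.76, 0.72, 0.62 and 0.61. Without imatinib 1, Nop14, Nop16, Ero1b, Pdia3 and Hyou1 no longer passed (adjusted p 0.051 to 0.061), without imatinib 2 Nop14, Pdia3 and Hyou1 did not (0.053 to 0.069), and Hyou1 also failed without control 2 (0.065) and without a filter on dim probes (0.058).

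Interferon-induced genes fell while T cell and macrophage markers rose (medians 1.95 and 2.20), with 20 down and 4 up of 37 (22 and 4 adjusted over the list alone), a median of -0.38 (-0.60 under median centring and -0.66 under spike-in scaling) and an adjusted p of 6.7e-05, or adjusted p = 0.23 with an estimated correlation. The antiviral GTPase genes Mx1 and Mx2 fell by 1.59 and 1.53 and the oligoadenylate synthetase gene Oas1a, uncertain as a member of a multigene family, fell by 1.45. Gbp6 (Mpa2l in the files) differed by 2.03 on a probe with an AG repeat of 12 bases and by 0.14 on another probe, which did not pass (adjusted p = 0.30). Among 27 regulators of apoptosis, 5 rose and 12 fell (5 and 13 adjusted over the list alone), with a median of -0.11 (from -0.02 under quantile normalization to -0.39 under spike-in scaling) and an adjusted p of 0.21. The death receptor gene Fas fell by 0.68 and the BH3 protein Bid fell by 0.72, and Bik, another BH3 protein, rose by 0.70. Of 18 heat shock genes, 5 rose and 9 fell (5 and 10 adjusted over the list alone), with a median of -0.22 (-0.44 under median centring and -0.50 under spike-in scaling) and an adjusted p of 0.29. Hspb1 and Hspa4l rose by 0.98 and 0.83, while Hsph1 and the co-chaperone Fkbp4 fell by 0.73 and 0.61. Bid and Fkbp4 no longer passed without imatinib 1 (adjusted p = 0.0504 and 0.082).

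Lysosomal genes, cytokine genes and immediate early genes rose in the arrays in which T cell and macrophage markers did (medians 1.95 and 2.20). Of 42 lysosomal genes, 25 rose and 2 fell (29 and 2 adjusted over the list alone), with a median of 0.33, which was 0.05 under spike-in scaling, and an adjusted p of 1.9e-06, or adjusted p = 0.22 with an estimated correlation. Besides Gpnmb and Cd63, the protease gene Ctsl and the hexosaminidase gene Hexa rose by 1.57 and 1.29. Of 24 cytokines of T cells and myeloid cells, 16 rose and 2 fell (17 and 2 adjusted over the list alone), with a median of 0.92, which was 0.43 with the other background correction, and an adjusted p of 6.7e-06, or adjusted p = 0.36 with an estimated correlation. After Ccl1, the chemokine genes Xcl1 and Ccl2 and the cytokine gene Lif rose by 3.48, 2.75 and 2.72. With normexp Xcl1, Ccl2 and Lif differed by 1.76, 1.60 and 1.18. Of 27 immediate early genes, 15 rose and 2 fell (15 and 4 adjusted over the list alone), with a median of 0.60, which was 0.32 under spike-in scaling, and an adjusted p of 0.00034, or adjusted p = 0.23 with an estimated correlation. The AP-1 member Fosl2 rose by 3.16, the nuclear receptor genes Nr4a2 and Nr4a1 by 2.01 and 1.53, and the phosphatase gene Dusp4 by 1.68.

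Oxidative stress genes rose as a list, with 11 up and 4 down of 24 (13 and 5 adjusted over the list alone) and an adjusted p of 0.018, or adjusted p = 0.35 with an estimated correlation; the median of 0.25 turned to -0.03 under spike-in scaling. Metallothionein 1, Mt1, rose by 2.59, heme oxygenase 1, Hmox1, by 2.39, Srxn1 by 2.23 and the quinone reductase gene Nqo1 by 2.20. The list did not pass without control 1 (adjusted p = 0.054), and T cell and macrophage markers rose in the same arrays (medians 1.95 and 2.20). Of 38 genes of the amino acid starvation response, 15 rose and 9 fell (16 and 10 adjusted over the list alone), and the median of 0.05 turned to -0.16 under median centring and -0.23 under spike-in scaling (adjusted p = 0.28). Under quantile normalization its median was 0.10 and it passed (adjusted p = 0.017). The secreted glycoprotein gene Stc2 rose by 3.28, the stress gene Nupr1 by 2.06, Vldlr by 1.82 and Gdf15 by 1.60. Of 31 genes of glycolysis and the hypoxia response, 12 rose and 6 fell (the same counts adjusted over the list alone), and the median of 0.07 turned to -0.14 under median centring and -0.21 under spike-in scaling (adjusted p = 0.096). This list passed, as higher than other genes, without imatinib 2 (adjusted p = 0.037), under quantile normalization (0.045), median centring (0.040) and spike-in scaling (0.026), and without a filter on dim probes (0.046). Ndrg1 rose by 3.23, the lactate transporter gene Slc16a3 by 2.29, the carbonic anhydrase gene Car9 by 1.40 and the collagen hydroxylase gene P4ha2 by 1.21.

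**Figure D3:**
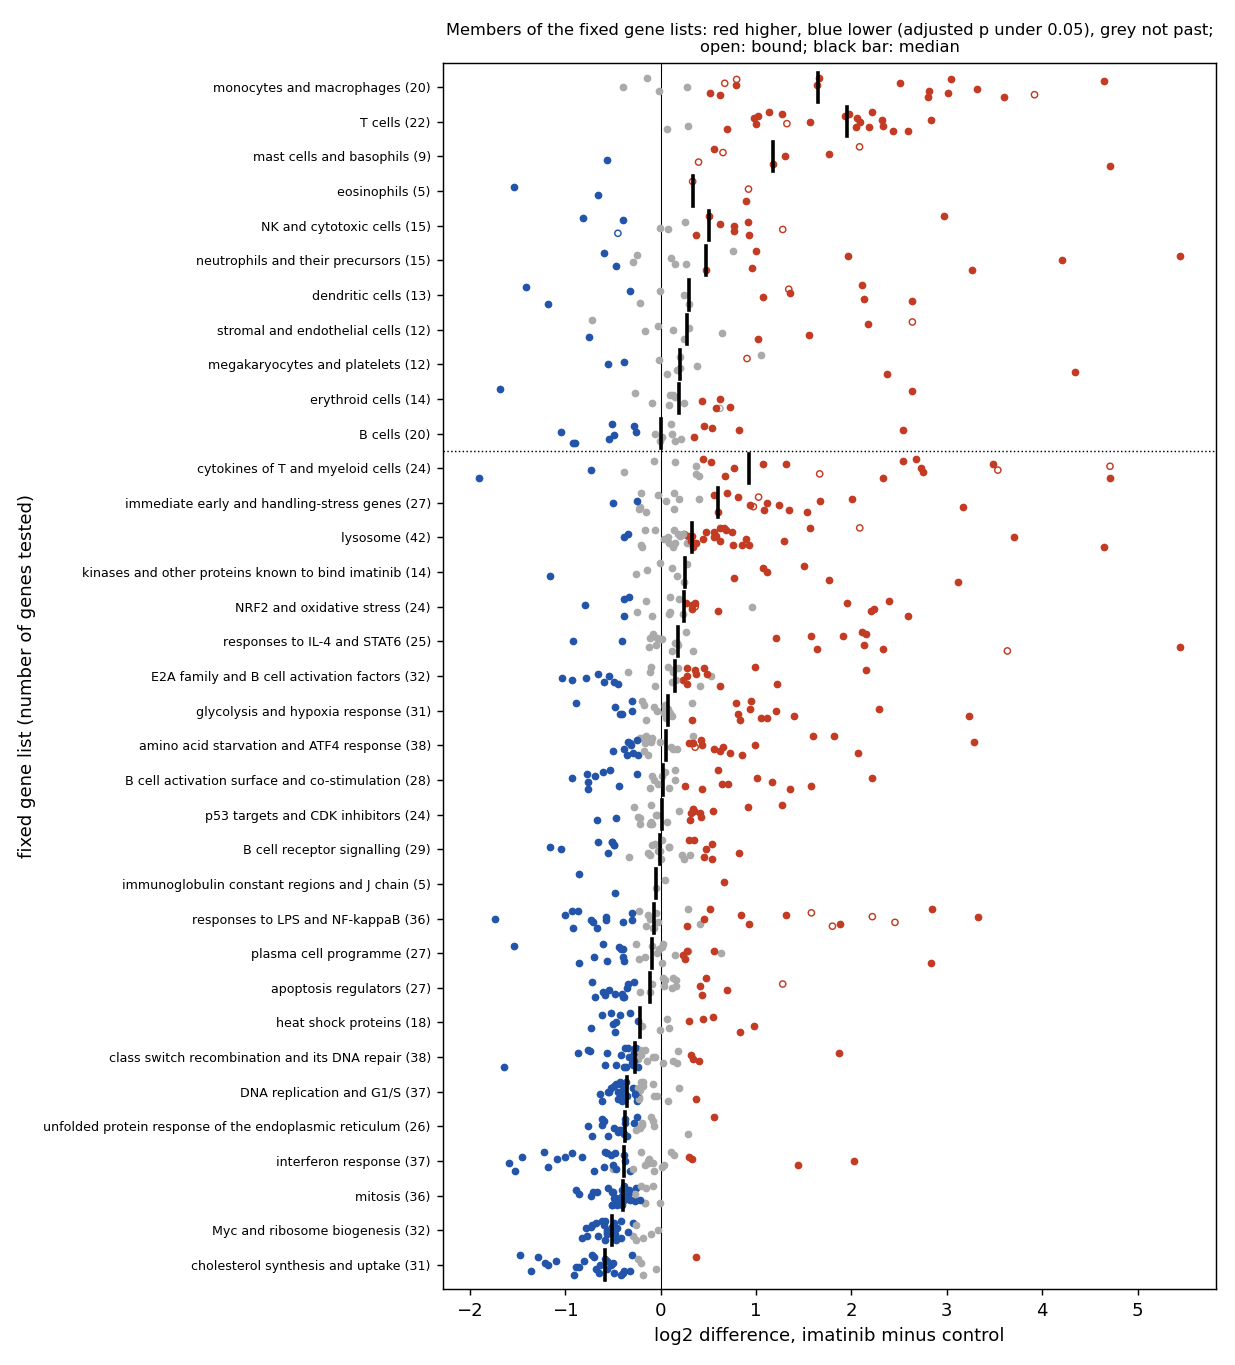
Log2 difference, imatinib minus control (x axis), of each tested gene of the 35 gene lists (y axis, number of genes tested in brackets), with cell type lists above the dotted line. Red and blue points passed an adjusted p of 0.05 as higher and lower, grey points did not pass, open points are bounds and black bars are medians with those members at their bound; these medians ran from -0.58 for cholesterol synthesis to 1.95 for T cells, and those of B cell, erythroid, platelet, stromal and 11 other lists change sign under another scaling or background correction.

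Markers of cell types that a spleen culture can hold were compared between the groups. Their RNA alone cannot tell a change in the share of a cell type from a change within its cells. Of 22 T cell markers, 20 rose and none fell (also adjusted over the list alone), with a median of 1.95 and an adjusted p of 2.2e-11, or adjusted p = 0.22 with an estimated correlation. Cd28 and the transcription factor Bcl11b rose by 2.84 and 2.59, Cd8a by 2.44 and Gata3 by 2.33, whereas the differences of Cd4 (0.07) and Cd247 (0.29) did not pass. Of 20 monocyte and macrophage markers, 16 rose and none fell (also adjusted over the list alone), with a median of 2.20 (1.65 with bounds) and an adjusted p of 2.3e-08, or adjusted p = 0.22 with an estimated correlation. After Gpnmb and Adgre1, the lysozyme gene Lyz1, which has a close relative and is uncertain, and the lectin gene Clec4n rose by 3.31 and 3.05, whereas C1qb (-0.02), Csf1r (0.28), Mpeg1 (-0.15) and Siglec1 (-0.40) did not pass. Of 20 B cell markers, 5 rose and 8 fell (6 and 8 adjusted over the list alone), with a median of 0.00 that turned to -0.21 under median centring and -0.28 under spike-in scaling, a mean of 0.02 and a test that pointed down (adjusted p = 0.79). Among them Fcmr, the IgM Fc receptor (Faim3 in the files), rose by 2.55, Cd22 fell by 1.05, the low-affinity IgE receptor Fcer2a fell by 0.92 and the adaptor Bank1 fell by 0.90, while Cd79a (-0.06) and Cd79b (-0.01) of the antigen receptor did not pass. The B cell list shares 13 genes with other lists, the T cell list 2 and the macrophage list 4. With the other background correction the medians were 1.21 for T cells and 0.75 for macrophages.

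Of 9 mast cell and basophil markers, 8 rose and 1 fell (also adjusted over the list alone), with a median of 1.30 (1.18 with bounds, and 0.66 with the other background correction) and an adjusted p of 9.9e-05, or adjusted p = 0.35 with an estimated correlation. After Ccl1 and Kit, the protease genes Prss34 and Tpsb2 rose by 1.30 and 1.18, both uncertain as members of a multigene family. Of 15 neutrophil markers, 7 rose and 2 fell (also adjusted over the list alone), with a median of 0.48, which was 0.20 to 0.26 under each other scaling and background correction, and an adjusted p of 0.033, or adjusted p = 0.43 with an estimated correlation. After Chil3 and Mmp8, the calcium-binding proteins S100a8 and S100a9 rose by 3.26 and 1.96, the latter with 1 control array above background. With normexp S100a8 and S100a9 differed by 1.41 and 0.56. Of 15 markers of NK and cytotoxic cells, 9 rose and 3 fell (10 and 3 adjusted over the list alone), with a median of 0.51, which was 0.23 under spike-in scaling, and an adjusted p of 0.018, or adjusted p = 0.36 with an estimated correlation. The kinase gene Txk rose by 2.97, the chemokine gene Ccl5 by 0.92 and Eomes, a transcription factor, by 0.91, while Gzmk differed by -0.81. Eomes no longer passed without imatinib 1 (adjusted p = 0.066), and Gzmk failed without imatinib 1 (0.089), control 1 (0.085) or control 2 (0.14), without a filter on dim probes (0.10) and with crossed pairing (0.053, chosen after seeing the data).

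The other marker lists did not pass, though several did under another setting. Of 13 dendritic cell markers, 6 rose and 3 fell (7 and 4 adjusted over the list alone), with a median of 0.30 and an adjusted p of 0.13. The list passed under median centring (median 0.09, adjusted p = 0.012), under spike-in scaling (median 0.02, adjusted p = 0.0067) and without a filter on dim probes (adjusted p = 0.040). Ccr9, Ccl17 and Ccl22 rose by 2.64, 2.13 and 2.11, and the growth factor receptor gene Flt3 fell by 1.41. Of 5 eosinophil markers, 3 rose and 2 fell (also adjusted over the list alone), with a median of 0.55 (0.34 with bounds, and 0.10 with the other background correction) and an adjusted p of 0.72. Il5ra, the IL-5 receptor, rose by 0.89, Prg2 fell by 1.53, Prg3 differed by -0.65 and Siglecf (Siglec5 in the files) was at least 1.89-fold higher. With normexp Siglecf differed by 0.43, less than its bound. Of 14 erythroid markers, 5 rose and 1 fell (also adjusted over the list alone); the median of 0.20 turned to -0.02 under median centring and -0.08 under spike-in scaling (adjusted p = 0.100, and 0.044 with the mean of the probes of a gene). Gata1 rose by 2.64, carbonic anhydrase 2, Car2, fell by 1.68, and the globin genes Hbb-b2 and Hba-a1, whose families have near-identical members and leave the targets uncertain, differed by 0.72 and 0.62. Of 12 platelet markers, 3 rose and 2 fell (also adjusted over the list alone); the median of 0.20 turned to -0.01 under median centring and -0.08 under spike-in scaling (adjusted p = 0.19, and 0.038 under spike-in scaling, as higher than other genes). After Pf4, Vwf differed by 2.37 with 1 control array above background, and P2ry12 and Itgb3 by -0.55 and -0.38. Of 12 stromal and endothelial markers, 4 rose and 1 fell (also adjusted over the list alone); the median of 0.27 turned to -0.01 under spike-in scaling (adjusted p = 0.077). It passed, as higher than other genes, without control 1 (adjusted p = 0.049), under median centring (0.021) and under spike-in scaling (0.015). Sparc, Esam and Vim rose by 2.17, 1.55 and 1.02, and Pecam1 differed by -0.75. Without imatinib 1, Siglecf, Prg3, Hbb-b2, Hba-a1, P2ry12, Itgb3 and Pecam1 no longer passed (adjusted p 0.052 to 0.10), and without imatinib 2 Hbb-b2, P2ry12 and Itgb3 did not (0.065 to 0.10). Itgb3 and Pecam1 also failed without control 1 (0.051 and 0.057), and P2ry12 and Pecam1 without control 2 (0.061 and 0.065). With the other background correction P2ry12 differed by -0.09 (0.29), and without a filter on dim probes Hbb-b2, P2ry12, Itgb3 and Pecam1 did not pass (0.052 to 0.065).

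Over the 35 lists, 18 passed with the preset correlation and 0 with an estimated correlation. With the latter, the lowest adjusted p was 0.22 and the lowest unadjusted p 0.019. A simulated list of independent genes shifted by -0.4 also got an adjusted p of 0.22 from camera with an estimated correlation. That test thus missed a true shift, and its values cannot tell for or against the calls at the preset correlation. In fry, 32 lists passed, and all 35 passed in its test for changes in either direction. Fry asks whether the genes of a list move on balance in 1 direction and compares them with no other genes. Since 41.1% of all 20500 genes passed singly, a pass in fry says little about a list.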

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

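The scaling on spike-in spots and the tests below were chosen only after the results were seen, except the test on other probes of the same genes, which was fixed before its result was seen.

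The E1A spike-in control spots, which the comparisons do not use, lay higher on the imatinib arrays after scaling to the 75th percentile, at 2.72 ± 0.061 against 2.44 ± 0.058 (SD, n = 2 arrays each, 8 transcripts), a log2 difference of 0.28. Before this scaling the 8 transcripts differed by -0.0014 to 0.15, so most of the difference came with the scaling. After it, the difference was 0.36 for the dimmest of them and 0.21 for the brightest.

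T cell and macrophage markers were higher with imatinib. A lower share of B cells as the only change would raise the markers of all other cell types alike, if B cells expressed none of them and all were above background. Not all markers met this. Ccr7 of the dendritic list and Tfrc of the erythroid list are also on the B cell activation list. Of 9 mast cell and basophil markers, 3 were dim in 1 group. The medians of 10 marker lists with 137 genes ran from 0.20 to 2.20. The lists differed more than with genes shuffled among them (permutation p = 0.002), which treats genes as independent though they are not. Because of such markers, this test cannot exclude a lower share of B cells, alone or beside other changes. A larger share of T cells stays open. Of the T cell markers, 86.4% lay within 1 of their median on the log2 scale, fewer than the share set for this explanation. Of these markers 0 fell, and Cd4 and Cd247 did not pass. A larger share of macrophages stays open too, with 45.0% of its markers that close to their median, also under the set share, and 0 that fell. Apoe, chosen after its value was seen, was higher by 2.51 and C1qb differed by -0.02. Neither can be told apart from a change within those cells, and the array scaling or background correction cannot be excluded as part of it, because the macrophage median was 0.75 under normexp, which shrinks differences of dim probes, while the scalings alone left both medians at 1.67 or more.

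Probes with a TG, AG or AAG repeat were higher with imatinib, by a median of 1.56 over 195 probes. The median lay at percentile 100 of 10000 random sets of probes without a repeat and of like signal (highest 0.03). The search for repeats began from bright probes that rose, so this comparison cannot decide on an expression-dependent bias. The median of the repeat probes stayed at 1.28 or more under each scaling and background correction. The 195 probes leave out AC and TC repeats, which had medians of -0.63 and -0.27. The high side of the next comparison was thus in part chosen. For 49 of the genes, other probes without a repeat had a median of 0.060, against 1.55 on their repeat probes. RNA other than that of the named genes on the repeat is therefore a candidate explanation, and no biological explanation was tested.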

How the results depend on the processing

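Spike-in scaling, crossed pairing, marked spots kept, lists without cell type members and repeat probes left out were chosen only after the results were seen; the other alternatives were planned. Of 146 named genes besides the study genes, 116 kept their direction and call under all alternatives that measured them and 0 changed direction; 30 no longer passed without imatinib 1, 16 without imatinib 2, 4 without control 1, 7 without control 2, 13 without a filter on dim probes, 2 with normexp, 2 with the replicate block and 1 each with median centring, spike-in scaling and crossed pairing. All 146 passed in the comparison of all 4 arrays, so that 0 changed direction was fixed in part by their choice. With repeat probes left out, 10299 probes changed, 13 of 24 and 5 of 11 lists passed, and the named probes of Ung, Tnfrsf9, Gbp6 and Dut gave no value. The cause of the changes below was not tested unless stated.

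With normexp, 793 probes were at least 2-fold changed, 681 higher and 112 lower; its offset shrinks differences of dim probes. Median centring gave 3124 higher and 10003 lower, 694 of them at least 2-fold, and spike-in scaling 2802 higher and 11739 lower, 890 of them at least 2-fold, and 8 cell type lists; both move every probe down. Without a filter on dim probes, 39337 probes were tested and 4971 changed, 2837 higher and 2134 lower. Leaving out 1 array gave 2529 to 8477 changed probes, 1908 to 4440 higher and 621 to 4037 lower, 307 to 535 at least 2-fold lower, and Tcf3 differences of -0.47 to -0.43, with fewer degrees of freedom. With an estimated correlation 0 of the 24 and 0 of the 11 lists passed, where camera at the preset correlation called 13 and 5. Camera with the estimated correlation also missed a simulated list shifted by -0.4 (adjusted p = 0.22). Fry, which tests another question, called 23 and 9.

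Across 25375 probes, which are not independent replicates, same-numbered arrays deviated from their group means with r = -0.069 and rho = -0.133. These values rest on a single difference between arrays in each group, so they cannot show whether the replicate numbers pair the samples. The replicate block left 7164 changed probes, 3655 higher and 3509 lower, and crossed pairing left 9630. The slide as a block was not run, since all arrays lay on 1 slide. Signal over background limits the falls and rises of probes that were dim in 1 group, which are bounds.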

Other observations

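The genes and the comparisons in this part were chosen only after their values were seen. Bounds in this part hold for the processed signal.

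Some genes that are known targets of the aryl hydrocarbon receptor were among those that rose; they were picked by their values, and no list of its targets was tested. Beside the receptor gene Ahr (4.01, and at least 4.25-fold on a second probe that was not above background in the control group), its repressor gene Ahrr rose by 3.14 (SE 0.066), and the monooxygenase genes Cyp1a1 and Cyp1b1 were at least 15.4-fold and 5.62-fold higher. Nqo1 rose by 2.20 and Tiparp, another target, by 0.65 and 0.89 on its probes (adjusted p = 0.0096 and 0.0056). Activity of the receptor was not analysed here.

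Single genes outside the lists also rose, picked by their values and not tested as a group. Lgals3, galectin 3, rose by 3.57 (SE 0.066), the fatty acid binding protein gene Fabp4 was at least 10.9-fold higher, and the receptor gene Cd300c2 (AF251705 in the files) was at least 11.3-fold higher. Fam20c, a kinase of secreted proteins, rose by 3.50, and by 2.77 on a second probe with 1 control array above background, and Pdpn, podoplanin, was at least 3.79-fold higher.

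The difference on probes with a TG repeat differed little between lengths from 12 bases up, with medians of 1.91 for 12 to 15 bases (36 probes), 1.97 for 16 to 19 (21), 1.96 for 20 to 29 (27) and 1.77 for 30 or more (25), and 0.35 for 8 to 11 bases (156). Probes with AC repeats, the complement of TG, had a median of -0.63, with 34 of 50 lower and 2 higher.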
